A study of Mus musculus with 2 samples.

How the data were processed

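Single-cell RNA was measured in 2 libraries of mouse 4T1 mammary tumour cells recovered from lungs, 1 from cells carrying GFP and 1 from cells carrying the Thy1.1 surface marker. Per the labels' protocols, both lines were mixed and injected into the tail vein of female BALB/c mice, at 500000 GFP cells and 25000 Thy1.1 cells per mouse, after transfer of 25000 pre-activated Jedi CD8+ T cells, which recognise GFP. Lungs were taken at day 7. Live CD45-negative cells positive for GFP or for Thy1.1 were sorted by flow cytometry, cells of different lungs were pooled, and libraries were made with the 10x Genomics 3' chemistry. The number of lungs pooled was not given in the sources used here.

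The authors deposited filtered matrices of raw UMI counts per gene and barcode, a UMI being a tag that marks a single captured molecule. Per the submitters' processing notes, these were made with Cell Ranger 8.0.1 on mm10. The annotation release was not given in the sources used here. Both matrices list the same 32285 genes, among which Thy1 is the mouse gene, and the GFP transcript was not analysed here. Of these gene identifiers, 32158 were found in GENCODE vM21 (GRCm38, the same assembly as mm10), from which the gene positions below were taken by identifier, counted from 1.

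Everything after the count matrices was computed here. Barcodes were kept with at least 1000 UMIs, at least 500 detected genes and at most 15% mitochondrial UMIs, which removed 1295 of 6824 barcodes of the GFP library and 1026 of 6042 of the Thy1.1 library. The mitochondrial limit was exceeded by 1208 and 949 of the removed ones. Scrublet, run per library with an expected doublet rate of 6%, marked 2 of 5529 and 0 of 5016 cells. A caller that marks so few has not worked on these libraries, so doublets were in effect not removed. Removing the 6% of cells with the highest scores was tried as an alternative.

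Kept cells of both libraries were scaled to 10000 UMIs, log transformed and clustered together on 2000 variable genes, 30 components and 20 neighbours with the Leiden method at resolution 1.0. Clusters were named from 16 marker lists, and a name needed at least 3 of a list's markers among the 20 genes with the largest fold. A cluster without them was called tumour-like, unless its depth was under 1/3 of that of its own library and no tumour marker led it. That depth rule was set after seeing the data and left 93 GFP and 66 Thy1.1 cells unnamed. Different clusters hold most tumour-like cells of each library, so cluster sizes are not compared. GFP cells made up most of clusters 2, 3, 5 and 6, led by class II, Krt14 and Cldn4, Ifit, and histone and class II genes. Thy1.1 cells made up most of clusters 0, 1, 4, 8 and 10, led by cell cycle genes (0, 1 and 4), by Mgp and Ccl2, and by Rps26.

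Gene levels are UMIs summed over the tumour-like cells of a library, as CPM (counts scaled to a common library total), with exact Poisson 95% intervals. Ratios of the GFP over the Thy1.1 library carry exact conditional binomial 95% intervals, and log2 ratios use a pseudocount of 1 CPM. With 1 library per group there is no replicate error, no test and no p-value. Intervals of levels, ratios and shares cover counting error only, and those of list medians cover the spread over members. A gene is called higher or lower by size: a ratio of at least 1.5, or of 1 over 1.5, with a counting interval that excludes 1 and at least 5 CPM in the higher library. Each of 22 gene lists is described by its median log2 ratio over members with at least 5 CPM, with the exact binomial 95% interval of the median over members, and by its percentile among 10000 random lists of the same size matched on mean CPM in 20 bins. The lists, the marker lists, the comparisons and the rule for named genes were fixed before the data were examined. Lists of 80 ribosomal protein genes and 13 mitochondrial genes were added after seeing the data. Symbols H2-L, Mx1, Mx2, Raet1a, Raet1b, Raet1c and H60a were not matched, and Ctgf and Cyr61 were matched as Ccn2 and Ccn1.

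Named genes are 13 fixed ones (among them Fas, Nr3c1, Tsc22d3, Fkbp5, Per1, Cd274, Irf1, B2m, H2-K1, H2-D1, Thy1 and Ptprc), the 12 with the largest and the 12 with the smallest log2 ratio among genes with at least 20 CPM in the higher library, up to 3 members of each list with the largest absolute log2 ratio, and the most abundant member of each marker list. Unnamed gene models were to be passed over, and none stood in the way. Some genes that this rule takes are not reported here. Shares of cells with a UMI, phase calls and list levels per cell were taken after thinning each cell to 5000 UMIs, which left out 138 GFP and 105 Thy1.1 tumour-like cells. Phases were called with scanpy's cell cycle scores from the S and G2 and M lists. Shares carry exact Clopper-Pearson 95% intervals.

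The alternatives were median-of-ratios and TMM scaling, each cell weighted alike, thinning, a stricter filter of at least 3000 UMIs, 1500 genes and at most 10% mitochondrial UMIs, doublets kept, all barcodes, cells called G1 only, equal phase shares, cells without a pan-leukocyte UMI, pseudocounts, CPM minimums of 1 and 20, and Leiden resolutions of 0.5 and 2.0. The calculation was tested on simulated counts for 9502 genes at the totals of the GFP and Thy1.1 libraries. The size rule called 50 of 50 genes changed 2.0-fold, 50 of 50 changed 4.0-fold, 50 of 50 changed 0.5-fold, 0 of 50 changed 1.25-fold and 0 of 9302 unchanged ones. The simulated counts held counting noise only, without variation between libraries or cells. They check the calculation and give no rate of false calls for these data. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5 and leidenalg 0.10.2 were used. Members of the Gbp, Ifit and class I H2 families have near-identical copies, and how the counting split shared reads is not given in the sources used here, so their single values are uncertain.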

Results

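4T1 cells, a mammary carcinoma line of BALB/c mice, were recovered from lungs at day 7 after injection as a mixture of GFP cells and Thy1.1 cells into mice carrying GFP-specific CD8+ T cells. GFP is the antigen of those T cells, and the Thy1.1 cells grew in the same lungs without it. The series title names glucocorticoid signalling, Fas and immune evasion during seeding of metastases. The comparison asks how tumour cells that carry the antigen differ from tumour cells that do not. There was 1 library per group, so no difference below has a replicate check. Of 9612 genes with at least 5 CPM in the higher library, 413 were higher and 131 lower in GFP tumour-like cells by the size rule. Counts per list below are to be read beside that share. The GFP library held 6824 barcodes and 155077103 UMIs, and the Thy1.1 library held 6042 barcodes and 154560722 UMIs.

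Both sorted populations consisted almost wholly of tumour-like cells. They made up 5354 of 5527 kept cells of the GFP library, or 96.9% (95% Clopper-Pearson interval 96.4 to 97.3), and 4814 of 5016 of the Thy1.1 library, or 96.0% (95.4 to 96.5). Endothelial-like cells numbered 44 and 80, fibroblast-like cells 17 and 34, alveolar type 2-like cells 9 and 12, and leukocyte-like cells 10 and 10. Sorting on GFP or Thy1.1 and against CD45 sets these shares. The leukocyte-like cells had a median of 2430 UMIs in the GFP and 21784 in the Thy1.1 library. They held the epithelial list at 8786 and 2935 CPM, against 5390 and 4360 in tumour-like cells, so neither set lacks epithelial RNA. Doublets with tumour cells are open in both, since doublets were in effect not removed. Tumour-like cells had a median of 25473 UMIs in the GFP and 29843 in the Thy1.1 library. Most GFP ones fell in clusters 2, 3, 5 and 6 and most Thy1.1 ones in clusters 0, 1, 4, 8 and 10, so the comparisons below set partly different clusters of this class against each other.

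The marker of the Thy1.1 line followed the labels. Thy1 had 2 UMIs over the GFP tumour-like cells and 103 over the Thy1.1 ones, a ratio of 0.0194 (0.0023 to 0.0719). After thinning, 0 of 5216 GFP cells held a Thy1 UMI, which allows a share of cells with a UMI of up to 0.0575% at 3 counts (0.0707% as the exact upper bound), and 24 of 4709 Thy1.1 cells did, or 0.510% (0.327 to 0.757). Unthinned shares were 0.0374% and 2.10%. Among endothelial-like cells, which should lack Thy1, 1 of 44 GFP and 0 of 80 Thy1.1 cells held a UMI, at median depths of 2200 and 1973 UMIs. Ptprc, which encodes the CD45 protein used to exclude leukocytes, had 3 and 2 UMIs.

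Interferon gamma target genes were far higher in tumour-like cells of the GFP library. Of 28 measured members of the interferon gamma list, 22 were higher there by the size rule and 0 lower, with a median log2 ratio of 2.59 (2.03 to 2.80). The largest differences were in Gbp4, a guanylate-binding protein, at 304 CPM against 13.6, a ratio of 22.3 (21.3 to 23.3), and in Cxcl9, a chemokine that attracts T cells, at 210 CPM against 9.91, a ratio of 21.2 (20.1 to 22.3). Cd274, which encodes the inhibitory ligand PD-L1, stood at 107 CPM (105 to 109) against 5.65 (5.28 to 6.05), a ratio of 18.9 (17.6 to 20.3). Irf1, an interferon-induced transcription factor, was 2.45 times higher (2.42 to 2.48).

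The list's median lay above those of all 10000 matched random lists, at percentile 100.0. Igtp (ratio 12.1), Iigp1 (11.6) and Ido1 (13.9), which encodes a tryptophan-degrading enzyme, were among the 12 genes with the largest log2 ratio, as were Ubd (23.9), Gbp2b (11.9) and Apol6 (16.9), which belong to no fixed list. The Gbp values are uncertain because the family has near-identical copies. A Cd274 UMI was seen in 31.0% (29.8 to 32.3) of thinned GFP cells and 2.65% (2.21 to 3.15) of thinned Thy1.1 cells, and in 57.9% and 10.3% without thinning. No class among these cells is sure to lack Cd274: endothelial-like cells held it in 16 of 44 and 11 of 80 cells, at median depths of 2200 and 1973 UMIs.

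Antigen presentation genes were higher in the GFP library as well. All 7 measured members of the MHC class II list were higher, with a median log2 ratio of 3.33 (2.81 to 3.43) at percentile 100.0. H2-Eb1 reached 530 CPM against 48.4, H2-DMb1 138 against 12.3, and Ciita, the class II transactivator, 24.0 against 1.44. In the MHC class I list 18 of 23 members were higher and 0 lower, with a median of 0.82 (0.61 to 1.42) at percentile 100.0. Tap1, a subunit of the peptide transporter, was 4.53 times higher (4.42 to 4.65), Tapbpl 3.50 times and Nlrc5, the class I transactivator, 3.40 times. The most abundant class I genes differed less: H2-D1 stood at 4965 against 3416 CPM, H2-K1 at 2659 against 1760 and B2m at 2346 against 1525, with ratios of 1.45, 1.51 and 1.54. Scaled without ribosomal and mitochondrial genes, H2-K1 at 1.46 and B2m at 1.49 left the size rule, and 15 of 23 members were higher. H2-K1 also left it under median-of-ratios scaling (1.493), TMM scaling (1.497), thinning (1.465) and in cells called G1 (1.375). B2m left it in cells called G1 as well (1.427).

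**Figure D1:**
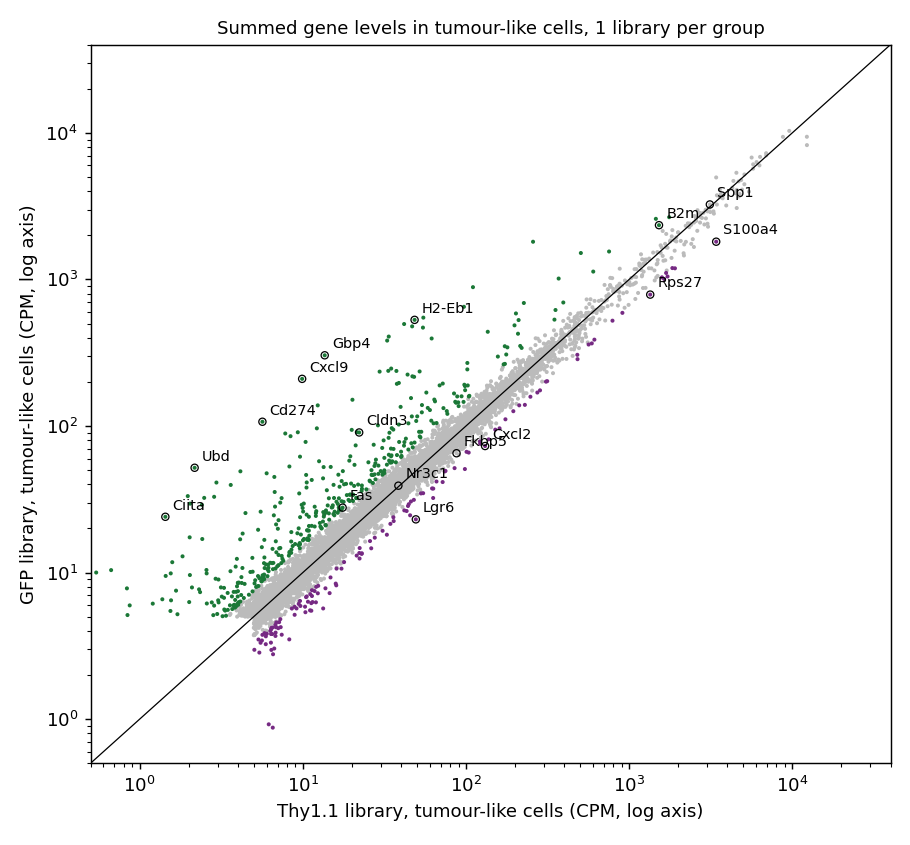
Summed level of each gene in tumour-like cells of the GFP library (vertical, CPM, log axis) against the Thy1.1 library (horizontal, CPM, log axis), 1 library each, with genes higher in the GFP library by the size rule in green, lower ones in purple and the line of equal levels. Gbp4 at 304 against 13.6 CPM and Cd274 at 107 against 5.65 lie far above the line, S100a4 at 1810 against 3417 lies below it, and Nr3c1 lies on it.

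Type I interferon genes were higher to a smaller degree, 21 of 24 members against 0 lower, with a median log2 ratio of 1.18 (0.70 to 1.58) at percentile 100.0. Zbp1, a sensor of nucleic acids, was 5.12 times higher, Ifit3 4.72 times and Ifit2 4.72 times. In the list of checkpoint and inhibitory ligands, 4 of 12 members were higher and 0 lower, with a median of 0.41 (0.07 to 0.91) at percentile 100.0. Besides Cd274 these included H2-T23, at 439 CPM against 136, and Lgals3, at 1132 against 603. The list shares Cd274 with the interferon gamma list and H2-T23 with the class I list. Among NK cell ligands 1 of 6 was higher, Clec2d at 24.8 against 10.6 CPM, while Nectin2 had a ratio of 1.37 and Pvr stood at 28.8 against 27.4, and the median was 0.04 (−0.07 to 1.16) at percentile 59.0.

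The interferon gamma list differed over a broad range of cells, while part of the GFP cells lay at the Thy1.1 level. After thinning to 5000 UMIs, the interferon gamma list had a median of 24 UMIs per GFP cell, with 10th and 90th percentiles of 4 and 53. The Thy1.1 cells had a median of 4, with percentiles of 1 and 11. At or below the Thy1.1 median lay 566 of 5216 GFP cells, 10.9% (10.0 to 11.7). This is a range on a continuous scale without a gap, and 740 GFP cells lay within 2 UMIs of that median. The most common GFP values lay there: 154 GFP cells had 4 UMIs, 90 had 10 and 126 had 27. At or below the Thy1.1 90th percentile of 11 UMIs lay 26.9% (25.7 to 28.1) of GFP cells. At or above the GFP median lay 91 of 4709 Thy1.1 cells, or 1.93% (1.56 to 2.37). The class II list had a median of 14 UMIs per GFP cell and of 1 per Thy1.1 cell.

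**Figure D2:**
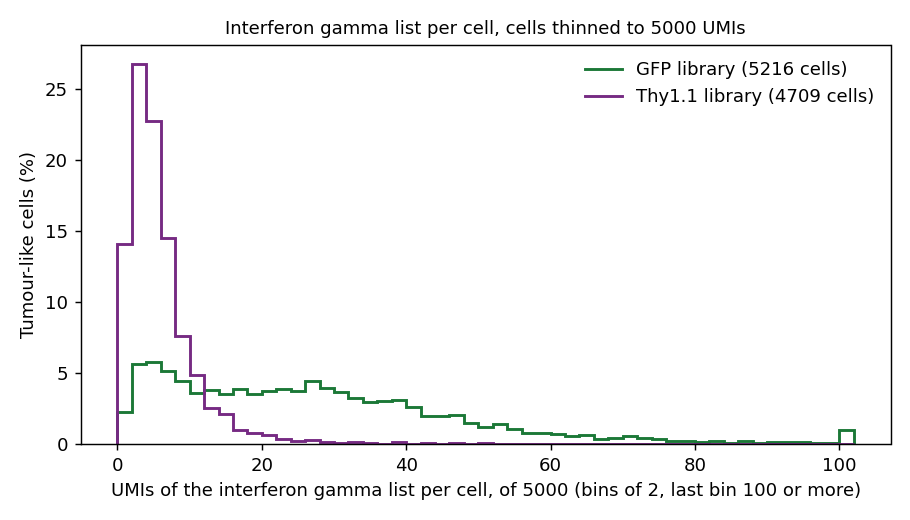
Share of tumour-like cells (vertical, %) by UMIs of the interferon gamma list per cell after thinning to 5000 UMIs (horizontal, bins of 2 UMIs), for 5216 cells of the GFP library in green and 4709 of the Thy1.1 library in purple. The Thy1.1 cells gather around a median of 4. The GFP cells, with a median of 24, spread widely, and their most common values lie at the Thy1.1 level.

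Fas, the death receptor engaged by Fas ligand on T cells, was higher in the GFP library. The gene, on chromosome 19 from 34290666 to 34327772 in mm10, had 27.7 CPM (26.9 to 28.6) against 17.5 (16.9 to 18.2), a ratio of 1.58 (1.51 to 1.66). In cells called G1 the ratio was 1.46 (1.35 to 1.58), short of the size rule. A Fas UMI was seen in 678 of 5216 thinned GFP cells (12.1% to 13.9%) and in 372 of 4709 thinned Thy1.1 cells (7.15% to 8.71%), and in 37.3% and 28.0% without thinning. Endothelial-like cells held one in 24 of 44 and 43 of 80 cells, at median depths of 2200 and 1973 UMIs, and so do not lack the gene. Of 19 measured members of the death receptor list, 4 were higher and 0 lower, with a median log2 ratio of 0.19 (−0.04 to 0.54) at percentile 99.99. Tnfsf10, which encodes the death ligand TRAIL, was 5.27 times higher and the Daxx transcript 1.77 times.

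Apoptosis regulators of the Bcl-2 family differed little, with 0 of 10 members past the size rule and a median of 0.05 (−0.07 to 0.26) at percentile 66.7. Over all genes 413 of 9612 were higher and 131 lower, so 0 of 10 does not set the family apart. Bak1 stood at 71.0 against 50.9 CPM, Bok at 154 against 208 and Bbc3 at 22.1 against 18.3. In the granzyme and perforin defence list 2 of 7 members were higher, Serpina3g at 29.0 against 2.41 CPM and Serpinb9, a granzyme B inhibitor, at 13.2 against 7.10. That list's median was 0.36 (−0.07 to 3.14) at percentile 99.94, and Ezr stood at 450 against 346 CPM. Over the alternatives the median ranged from 0.14 over members with at least 20 CPM to 0.40 in cells called G1.

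Glucocorticoid receptor levels were alike in both libraries, and 2 of 19 of its target genes passed the size rule. Nr3c1, which encodes the receptor, on chromosome 18 from 39410545 to 39519421, had 39.2 CPM (38.2 to 40.2) against 38.5 (37.5 to 39.5), a ratio of 1.02 (0.98 to 1.05). Fkbp5, a receptor target that restrains the receptor, was lower at 65.2 against 87.5 CPM, a ratio of 0.745 (0.726 to 0.765) that did not reach the size rule. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, stood at 37.4 against 32.7 CPM, and Per1 had a ratio of 0.991 (0.943 to 1.04). The 2 members of the glucocorticoid response list past the rule were higher, with 0 lower: Lcn2, at 528 against 210 CPM, which is also in the NF-kB list, and Bcl6, at 16.7 against 10.9. Scaled without ribosomal and mitochondrial genes, Bcl6 had a ratio of 1.49 and left the rule, so 1 of 19 stayed. Tgm2 stood at 70.1 against 48.0 CPM. The list's median log2 ratio was 0.11 (−0.01 to 0.42) at percentile 97.9, and it ranged from 0.06 in that scaling to 0.25 as the mean of each cell's CPM.

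None of 10 members of the list of the receptor and steroid handling passed the size rule, as few of all genes did. The list's median was 0.04 (−0.02 to 0.10) at percentile 67.0. The members farthest from equal were Ncoa1 at 19.5 against 16.9 CPM, Stip1 at 151 against 141 and Abcb1b at 80.7 against 86.0.

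Epithelial genes were higher in the GFP library, 15 of 22 members against 0 lower, with a median log2 ratio of 0.90 (0.38 to 1.38) at percentile 100.0. The most abundant members differed little, Krt18 at 1967 against 1825 CPM and Krt8 at 1750 against 1662, both named after their values were seen, so the summed list was only 1.24 times higher (1.23 to 1.24), with a median of 21 against 19 UMIs per thinned cell. Cldn3 and Cldn4, components of tight junctions, stood at 90.3 against 22.2 and 62.1 against 19.6 CPM. Mesenchymal genes lay slightly lower, 0 of 19 higher and 3 lower, with a median of −0.09 (−0.33 to −0.01) at percentile 2.30. The lower ones were Ccn2, a matricellular protein gene, at 2.77 against 6.57 CPM, S100a4 at 1810 against 3417 and Mmp3, a matrix metalloproteinase gene, at 49.0 against 74.0.

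Genes lower in the GFP library differed by smaller ratios than the interferon genes did. Among genes with at least 20 CPM in the higher library, the smallest log2 ratios, with ratios of 0.468 to 0.589, were those of 12 genes that included Lgr6, Lgals7, S100a4, H19, Cxcl2, Serpine2, Col5a1, Tnnt3, Fmc1, Rps27 and Cops9. Lgr6, a receptor for R-spondins, stood at 23.1 against 49.3 CPM and H19, an imprinted long noncoding RNA, at 24.6 against 45.5. Cxcl2, a neutrophil chemokine gene, stood at 73.0 against 131 CPM, and Rps27 at 788 against 1347.

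Oxidative phosphorylation genes were lower in the GFP library, with a median log2 ratio of −0.28 (−0.44 to −0.04) at percentile 0.0, where 3 of 26 members passed the size rule as lower and 0 as higher. These were Cox7c at 388 against 613 CPM, Ndufb2 at 78.5 against 122 and Ndufa4 at 592 against 909. Ribosomal protein genes, a list added after seeing the data, had a median of −0.21 (−0.30 to −0.09) at percentile 0.0, with 8 of 80 lower and 0 higher. Scaled without ribosomal and mitochondrial genes, 5 of 26 oxidative phosphorylation and 15 of 80 ribosomal protein genes were lower. The 13 mitochondrially encoded genes, also added, had a median of −0.03 (−0.44 to 0.07) at percentile 28.3, with 1 lower. Oxidative phosphorylation and ribosomal protein genes are short, with a median transcript length of 887 bases against 3130. Other genes had a median of −0.43 up to 500 bases (40 genes), −0.13 from 500 to 750 (178) and 0.02 from 750 to 1000 (310).

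Cell cycle genes lay slightly lower in the GFP library. The S phase list had a median log2 ratio of −0.15 (−0.21 to −0.09), below all random lists, with 1 of 42 members lower by the size rule, Ccne2 at 6.41 against 9.61 CPM. Ccne2 sat at the edge of the rule and lost its call under several alternatives. Cdca7 stood at 20.9 against 30.4 and Hells at 103 against 140 CPM. The G2 and M list had a median of −0.08 (−0.11 to −0.04) at percentile 0.03 and 0 of 50 members past the rule, with Mki67, a proliferation marker, at 129 against 166 CPM, Anp32e at 151 against 192 and Cks1b at 368 against 451. With both libraries weighted to the same shares of the phases, the medians of the S list and the G2 and M list were 0.0011 and 0.0251. Within cells called G1 they were −0.26 and −0.18. The G1 call rests on the genes of these lists, so it cannot show whether a difference persists within G1. Phase calls put 42.0% (40.7 to 43.4) of thinned GFP cells in G1, 18.6% in S and 39.3% in G2 or M, against 28.1% (26.8 to 29.4), 24.6% and 47.3% of Thy1.1 cells. Unthinned shares in G1 were 40.6% and 27.6%. Free RNA enters such calls, and whether it differs between the libraries is open.

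**Figure D3:**
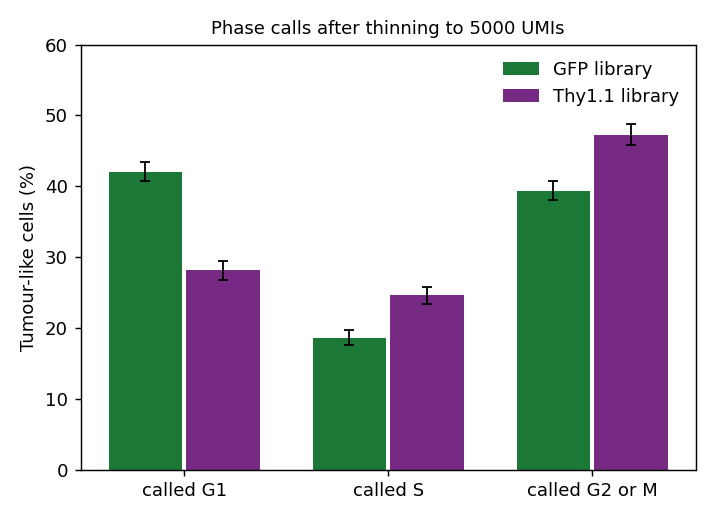
Share of tumour-like cells called G1, S, or G2 or M (vertical, %) in the GFP library (green, 5216 cells) and the Thy1.1 library (purple, 4709 cells) after thinning to 5000 UMIs, with exact 95% binomial intervals as error bars. G1 calls made up 42.0% of GFP and 28.1% of Thy1.1 cells.

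Inflammatory and stress lists differed in a few members. In the NF-kB and TNF list 5 of 23 were higher and 1 lower, Cxcl2, with a median of 0.20 (−0.18 to 0.49) at percentile 100.0. Over the alternatives that median ranged from 0.07 over members with at least 20 CPM to 0.27 in cells called G1. Il1a, which encodes a pro-inflammatory cytokine, stood at 12.9 against 1.83 CPM and Cxcl5 at 26.1 against 10.0. Immediate early genes had a median of 0.21 (0.02 to 0.43) at percentile 100.0, with 1 of 20 higher, Klf2 at 263 against 170 CPM, while Nr4a1 stood at 53.4 against 77.8 and Dnajb1 at 87.7 against 62.3. The unfolded protein response list had a median of 0.13 (0.02 to 0.36) at percentile 99.2, and 3 of 20 were higher: Trib3 at 16.3 against 6.83, Ddit3, which encodes CHOP, at 55.7 against 27.8 and Sesn2 at 5.97 against 3.76 CPM. After thinning, Sesn2 had a ratio of 1.49 and left the rule. In cells called G1 the list's median was 0.04, with 4 of 20 higher.

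Apart from oxidative phosphorylation, the metabolic lists lay close to equal over all tumour-like cells. Hypoxia and glycolysis genes had a median of 0.03 (−0.14 to 0.12) at percentile 67.4, with 1 of 22 lower, Egln3 at 26.6 against 41.9 CPM, while Hk1 stood at 67.0 against 54.7 and Hk2 at 67.2 against 56.4. Cholesterol synthesis genes had a median of −0.06 (−0.14 to 0.07) at percentile 3.86 and 0 of 18 past the rule, with Fdps at 306 against 267 and Insig1 at 26.6 against 30.5 CPM. In cells called G1 that median was −0.30, with 3 of 18 lower. NRF2 targets had a median of −0.07 (−0.23 to 0.02) at percentile 6.94, with 3 of 15 lower, Gstm1 at 4.17 against 7.07, Slc7a11 at 3.44 against 5.61 and Gsta4 at 4.59 against 7.16 CPM. After thinning, Gstm1 had a ratio of 0.827 (0.6475 to 1.0557) and lost its call.

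**Figure D4:**
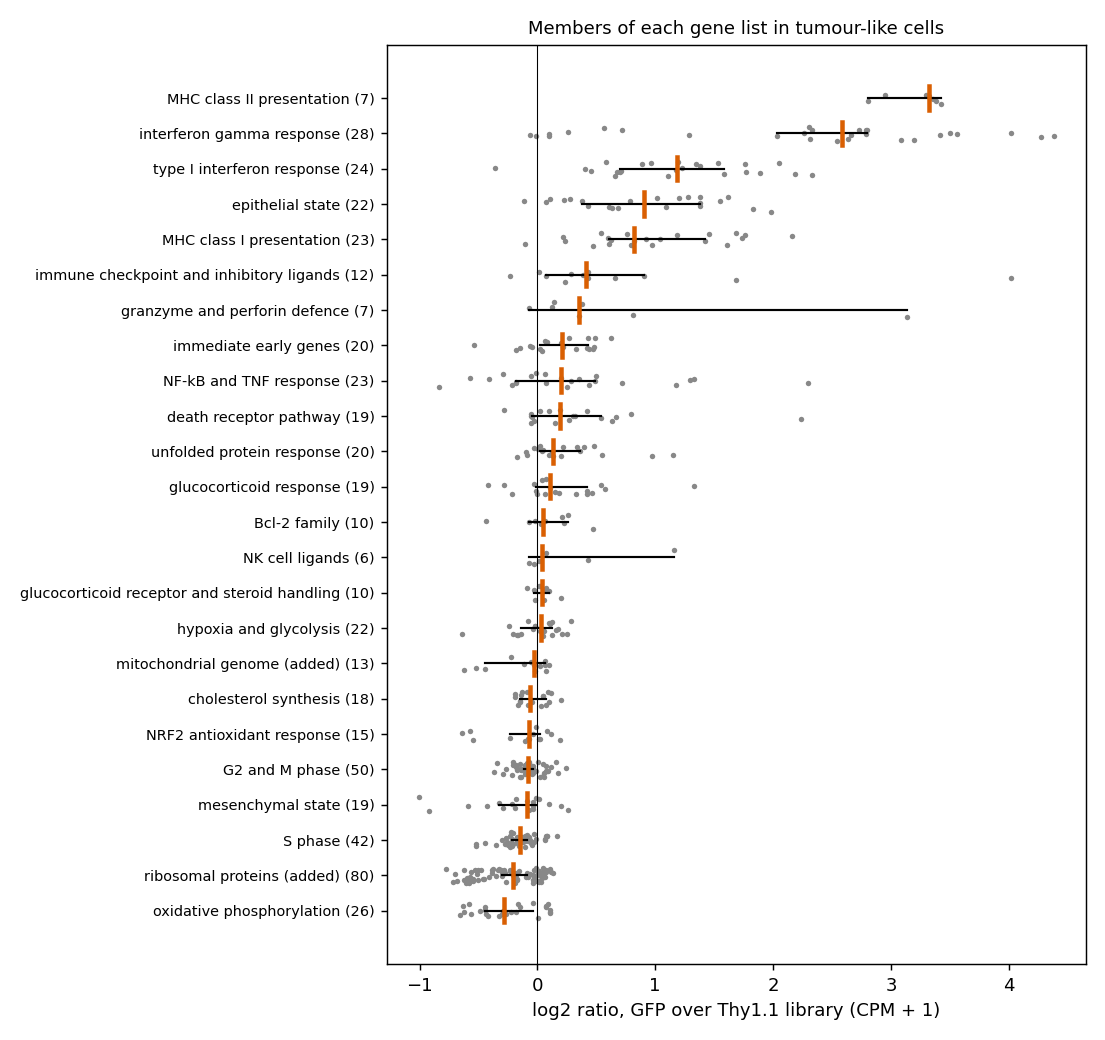
Log2 ratio of each list member with at least 5 CPM (horizontal, GFP over Thy1.1 library, CPM + 1) by gene list (vertical, number of members in brackets), with grey points for genes, orange bars for list medians and black lines for the exact binomial 95% interval of the median over members. The class II list at 3.33 and the interferon gamma list at 2.59 stand highest, and oxidative phosphorylation at −0.28 stands lowest.

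Markers of other cell types were measured in the tumour-like cells. The most abundant pan-leukocyte gene was Coro1a, at 0.995 CPM in the GFP and 1.54 in the Thy1.1 library. Other immune lists were led by Trac at 1.17 and 1.28 CPM, Cd79a at 0.434 and 0.455, S100a8 at 0.261 and 0.261, and Fabp4 at 0.0802 and 0.120. The macrophage and monocyte list was led by Cd14 at 18.7 against 12.5 CPM and the dendritic list by Fscn1 at 120 against 137. Lung and stromal lists were led by Abca3 at 17.4 and 16.4 CPM, Emp2 at 145 and 122, Scgb1a1 with 210 and 179 UMIs, Egfl7 at 6.30 and 7.79, Pdgfra at 7.34 and 8.94, Notch3 at 1.43 and 0.388, and Msln at 77.6 and 62.5. Alas2 led the erythroid list at 0.240 and 0.314, and Spp1 the tumour list at 3248 and 3125 CPM.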

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

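The test of the pan-leukocyte genes and the question of the lines before injection were chosen only after the interferon result was seen. A signal outside the main measurement appeared in the barcodes removed by the cell filter, mostly for mitochondrial UMIs. Their summed interferon gamma list was 3.82 times higher in the GFP than in the Thy1.1 library (3.69 to 3.95).

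The interferon gamma list was higher in tumour-like cells of the GFP library, with a median log2 ratio of 2.59. The endothelial-like cells had the summed list 1.68 times higher (1.56 to 1.81) against 4.84 times in tumour-like cells. This argues against a difference of the same fold in every cell type. Their levels were 11430 against 6812 CPM, and those of tumour-like cells 5301 against 1095. A similar amount added in endothelial-like and tumour-like cells is therefore not excluded. Fibroblast-like cells had the list 1.45 times higher (1.29 to 1.64). Their levels were 3994 against 2748 CPM, a smaller gap than in endothelial-like or tumour-like cells. Their type I list was 0.72 times as high (0.58 to 0.88), their class I list 0.83 times and their class II list 2.57 times. Unnamed cells had the interferon gamma list 3.21 times higher. Tumour markers summed to 3313 and 2628 CPM in fibroblast-like and 2258 and 2674 in unnamed cells. Tumour-like cells had 8158 and 7216, so tumour RNA may enter these ratios. The 10 and 10 leukocyte-like cells had the interferon gamma list 2.86 times higher (2.42 to 3.38) and the class II list 7.88 times. But they also had the macrophage and monocyte list 6.41 times higher, so they differ in make-up and decide nothing. RNA from leukocytes is argued against by the summed pan-leukocyte genes in tumour-like cells, 0.80 times as high in the GFP library (0.676 to 0.945). The macrophage and monocyte list, led by Cd14, was 1.41 times higher. After thinning, the interferon gamma median was 2.51. CPM already scale by total UMIs, so thinning tests only the weight of deep cells, which is argued against as the cause. Recognition of GFP by the transferred T cells, a hypothesis, cannot be told apart from a difference between the 2 lines that was there before injection, because 0 libraries analysed here came from mice without transferred T cells, nor from the injected number, 500000 GFP against 25000 Thy1.1 cells per mouse.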

How the results depend on the processing

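Doublet scores, the ribosomal cluster and the scaling without ribosomal and mitochondrial genes were chosen as alternatives after seeing the data. Over 14 alternatives and other CPM minimums, 343 list medians stayed within the spread over their members, 7 moved beyond it and 2 did so with a change of sign. The 2 were the cell cycle lists with both libraries weighted to the same phase shares, at 0.0011 for S phase and 0.0251 for G2 and M, which by construction removes a difference in phases. The S phase median was −0.23 as the mean of each cell's CPM and −0.26 in cells called G1. The G2 and M median was −0.19 as the mean of each cell's CPM, −0.18 after thinning, −0.18 in cells called G1 and −0.13 scaled without ribosomal and mitochondrial genes. Phases are called from the S and the G2 and M lists, so medians and size calls of these lists within G1 are conditioned on their own genes. The cholesterol synthesis median was −0.30 in cells called G1. The share of tumour-like cells became 95.02% (GFP) and 90.3% (Thy1.1) at Leiden resolution 2.0, 99.4% and 98.8% with the stricter filter, and 96.3% (GFP) with doublets kept. The share called S was 21.03% (GFP) and 26.6% (Thy1.1) without thinning and 17.3% and 20.7% at 2000 UMIs. The cause of these shifts was not tested. Of single gene ratios, 858 stayed within counting error and 668 moved beyond it, and 23 changed sign, 0 of them of genes past the size rule. Among them was Nr3c1, at −0.02 when scaled without ribosomal and mitochondrial genes. Another 5 medians crossed 0 within the spread, those of hypoxia and glycolysis under 3 settings and of NK cell ligands and of the receptor and steroid handling when scaled without ribosomal and mitochondrial genes. Size calls were compared only where UMIs are summed. Scaled without ribosomal and mitochondrial genes, the lower ribosomal protein genes went from 8 to 15, oxidative phosphorylation from 3 to 5, S phase from 1 to 2 and immediate early genes from 0 to 1, and higher glucocorticoid response genes from 2 to 1. In cells called G1, lower ribosomal protein genes went to 14, oxidative phosphorylation to 7, S phase to 4, G2 and M from 0 to 6, cholesterol synthesis from 0 to 3, and Bcl-2 family, type I interferon and glucocorticoid response from 0 to 1 each, while higher genes went from 0 to 1 in G2 and M and from 1 to 2 in immediate early genes. After thinning, lower oxidative phosphorylation genes went to 5, lower NF-kB genes from 1 to 0 (Cxcl2 at 0.674) and higher immediate early genes to 2, lower mitochondrially encoded genes went from 1 to 0, and Gstm1 lost its call at 0.827. Lower NF-kB genes went from 1 to 2 under 7 alternatives. Ccne2, with a main ratio of 0.6665 at the edge of the rule, lost its call under 6, with 0 lower S phase genes left under 4 of them, and 4 type I interferon genes lost theirs in cells called G1. No paired analysis was possible because each group has 1 library. Depth limits Thy1 and Ptprc, which had at most 103 UMIs per library.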

Other observations

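The test of the epithelial list in cells at the low interferon level was chosen only after the Thy1 result and the other lists were seen. In tumour-like cells at or below 4 interferon gamma list UMIs of 5000, 566 GFP and 2516 Thy1.1 cells, the interferon gamma list came closer by construction, at a median log2 ratio of 0.35. The class I list had a median of 0.03 (−0.02 to 0.18) against 0.82 over all cells, and the class II list one of 0.57 against 3.33. Epithelial genes stayed apart. Epcam stood at 392 against 152 CPM in these cells, Cdh1, which encodes E-cadherin, at 68.6 against 26.0 and Krt14 at 210 against 47.2, genes chosen after their values were seen. Rps27 stood at 774 against 1380 CPM and Lgr6 at 21.1 against 44.4. The S phase list had a median of −0.14 and ribosomal protein genes one of −0.21 in these cells, against −0.15 and −0.21 over all cells. The G2 and M list had one of 0.07 (0.04 to 0.12) in them against −0.08 over all cells.

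Over cells within a library, the interferon gamma list went with the class II list, with a Spearman correlation of 0.53 in the GFP and 0.24 in the Thy1.1 library, shared members left out. With the epithelial list the correlations were −0.03 and −0.03, and with the glucocorticoid response list 0.17 and 0.35. Cells are not independent replicates, so these describe the 2 libraries only. Endothelial-like cells of the GFP library had the class II list 1.249 times higher (1.11 to 1.40) than those of the Thy1.1 library, over 44 and 80 cells. Leaving out the Thy1.1 cells with at least 1% alveolar type 2 UMIs, which leaves 78 and was chosen after seeing them, that ratio was 1.46 and the interferon gamma ratio 1.62 (1.503 to 1.75).

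Of 80 ribosomal protein and 26 oxidative phosphorylation genes, 8 and 3 were lower by the size rule, 18 and 7 had log2 ratios above 0, and both medians were below 0. They are short, with a median transcript length of 887 bases against 3130 in other genes. Other genes had a median log2 ratio of −0.43 up to 500 bases (40 genes), −0.13 from 500 to 750 (178) and 0.02 from 750 to 1000 (310). Against the 50 other genes nearest in length, the ribosomal protein and oxidative phosphorylation genes had a median of −0.14 (−0.20 to −0.09). The unmatched difference was −0.25. The bound set before the result was 0.5 of the unmatched difference, and the interval spans it, so length as the main cause cannot be told apart from other causes. After thinning, the difference from all genes was −0.30, against −0.25 before. Thinning weights all cells of at least 5000 UMIs alike, so shallow cells above that limit count more. It therefore cannot decide on cells of low depth. The low-depth cluster led by ribosomal protein genes is argued against by a difference of −0.22 without it. What remains open includes a difference between the lines or the library preparations, which was not tested.

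Part of the GFP library, 10.9% of its cells (10.0 to 11.7), sat at or below the Thy1.1 median of the interferon gamma list after thinning. Thinning gives every cell it keeps the same number of UMIs, so unequal depth does not enter this share. The share is the observation itself, so it cannot decide on depth in any other way. Whether counting noise at the thinned depth puts some of these cells there was not tested. If these GFP cells were Thy1.1 cells sorted into the GFP library, their epithelial genes would sit at the Thy1.1 level. The epithelial list was instead higher in them than in Thy1.1 cells at the same interferon level, with a median log2 ratio of 1.01 (0.49 to 1.503). That argues against Thy1.1 cells as all of them. These levels are summed over the cells, so they cannot say what most of them are. The test of Thy1, set before its result was seen, asked for a rate with an upper bound below 0.5 of that of the Thy1.1 library and missed it: the ratio was 0.0928 (0.0023 to 0.529), from 1 UMI. A candidate explanation is that some GFP cells met no T cells or did not respond to interferon; no value here tests it, and the GFP transcript was not analysed here.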
